A study of Mus musculus with 4 samples.

How the data were processed

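Poly(A) RNA of mouse bone marrow-derived macrophages was sequenced from 4 libraries: 2 controls (Mettl3fl/fl) and 2 knockouts (Mettl3fl/fl with LysM-cre), per the labels. The macrophages had been grown with M-CSF and co-cultured for 24 h with MC38, a mouse colon carcinoma line. Per the labels' protocols the libraries were made with dUTP, which marks the strand, and read as pairs of 150 bases. Trimming with cutadapt 1.9, alignment software HISAT2 2.0.4 and StringTie 1.3.4d are named in the submitters' processing notes, as are edgeR and DESeq2 without a version. Whether counting used the strand, and how reads with several matches were treated, is not given in the sources used here.

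The authors deposited 1 table of 55401 genes with, for each library, an estimated count and an FPKM value per gene, per the file headers. The estimated counts, as deposited, were whole numbers and were not normalized. Between 38.7% and 39.5% of the low counts (1 to 24) were multiples of 4, and about 1128 genes stood at a count of 4 in the first control, against 359 at 3 and 191 at 5. A read pair may therefore have given about 4 counts in part of the genes, though most low counts were not multiples of 4, and the number of fragments behind a count is not known. The deposited FPKM values were the authors' own, scaled by gene length and library size, with 0 written as 0.0001. A further 4 columns of values, from 2 libraries whose names matched no sample, were not used in any step. The genome build is not given in the sources used here. Of the 55141 gene identifiers shared with GENCODE M21 (GRCm38), 94.2% had the same start and end, and coordinates below are those of the deposited table.

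The total count was 55100415 in control 1, 61075754 in control 3, 62563556 in knockout 1 and 79209870 in knockout 3. If each pair gave 4 counts, this is 13.8 M to 19.8 M read pairs. The level that 12 counts (3 read pairs, if each gave 4) give was 0.218, 0.196, 0.192 and 0.151 CPM (counts scaled for library size) in the same order. Such floors cover counting error only, since PCR copies were not marked.

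The design was fixed before the data were examined. It had foreseen limma on FPKM, with edgeR instead if the table held counts. Because it did, the estimated counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, default settings), as deposited since they were already whole. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, and standard errors were taken from the fold change and its F statistic. Gene lists (37, fixed before the data were examined) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2. The preset correlation between genes was 0.01, and adjustment ran over all lists with at least 5 tested members. Each list was tested again with an estimated correlation and with fry. With an estimated correlation camera has only the few residual degrees of freedom of the 4 libraries, so it could call few lists. It called 0 lists between genotypes and 0 between library numbers, where all 36 cell cycle genes lay below 0. A call lost in that test is therefore not evidence against a list. DESeq2 1.42.0, other scalings, filters, pseudocounts, variance models, a replicate block and the omission of each library in turn were set as alternatives before the data were seen. A further 6 settings were added after the data were seen: limma on log2(FPKM + 1) with and without the block, limma voom with the block, DESeq2 with the block, counts divided by 4, and the bias-adjusted form of edgeR's test. Term enrichment had been planned only for at least 10 changed genes and was not run.

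The genes named in the text were chosen by a rule. It took Mettl3, Lyz2 and Spred2, then the 12 genes per direction with the largest change among those that passed the test. Where none passed, it took the 12 with the smallest unadjusted p per direction, leaving out predicted symbols (Gm with digits, or ending in Rik). Of each described list it took up to 4 changed members or, where none changed, the 2 with the highest mean FPKM. Names outside this rule are marked as chosen after their values were seen.

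The tests were tried on simulated counts for the 17260 tested genes, drawn from the mean of each library number and the blocked dispersions. Of genes changed 2-fold, 4-fold and 8-fold, edgeR without a block called 0%, 0% and 18.2%. DESeq2 called 4.5%, 65.7% and 63.6% of them, and edgeR with the replicate block 20.9%, 73.1% and 71.2%. A simulated list of 40 genes raised 1.75-fold was called by camera, and 0 of 20 unchanged lists were. The simulated genes were drawn independently, while the estimated correlation was 0.55 in the interferon-stimulated list and 0.85 among mitochondrial mRNAs, so this says nothing about false calls of correlated lists. This simulation replaced a first one that left out the difference between library numbers, in which edgeR without a block called more of the changed genes. The calls among the 17020 unchanged genes numbered 1 for edgeR, 4 for DESeq2 and 16 for edgeR with the block. Sequences of gene copies were compared with BLAST+ 2.17.0 on GENCODE M21 transcripts.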

Results

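Gene expression was measured by RNA sequencing in bone marrow-derived macrophages from 8-week C57BL/6 mice after 24 h of co-culture with MC38 colon carcinoma cells. There were 2 control libraries (numbered 1 and 3), from mice with a floxed Mettl3 gene, and 2 knockout libraries (numbered 1 and 3), from mice that also carried the LysM-cre driver. Mettl3 encodes the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA, and the driver is expressed in myeloid cells. The labels call the libraries biological replicates, and do not say whether equal numbers mark a shared litter or day. Between 20650 and 20986 genes had a count in each library, at total counts of 55100415 to 79209870. Libraries with the same number resembled each other most. The Y-linked Ddx3y stood at 71.1 and 89.0 CPM (counts scaled for library size, here by the total count) in control 1 and knockout 1, and at 0.311 and 0.139 in control 3 and knockout 3. Xist, the X-inactivation transcript, stood at 0.581 and 0.623 in the libraries numbered 1 and at 1370 and 1161 in those numbered 3 (both genes chosen after their values were seen). By these levels the libraries numbered 1 had the pattern of male cells and those numbered 3 that of female cells, so number and sex coincide. Values within each number are therefore given beside the pooled ones for the lists that were called and for the genes studied most closely.

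The targeted gene was examined first. Mettl3 (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128, minus strand) stood at 18.3 and 23.2 CPM in controls 1 and 3 and at 13.9 and 19.6 CPM in knockouts 1 and 3. Its log2 fold change was -0.31 ± 0.27 (SE, n = 2 per group; edgeR unadjusted p = 0.306, adjusted p = 1), so the groups overlapped. Within the numbers the difference was -0.40 for number 1 and -0.25 for number 3. The fold change was -0.131 without control 3, -0.07 without knockout 1 and -0.584 without knockout 3. Leaving out 1 library mixes library number with genotype, here and for all values of this kind below. A count over the whole gene includes exons outside any deleted part, and the labels do not name the deleted exons, so this value does not check the labels. Mettl3 overlaps Tox4 on the opposite strand. Lyz2, the lysozyme gene that houses the driver (chromosome 10, 117277331 to 117282321), stood at 22070 and 40810 CPM in the controls and at 25450 and 25790 CPM in the knockouts. Its log2 difference was 0.21 within number 1 and -0.66 within number 3, and the fold change of -0.30 turned to 0.215 without control 3 and was -0.665 without control 1. Lyz2 had been set in advance as a check of the driver, but with opposite signs it does not check the labels either.

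The question behind the comparison, as far as the study is known, was how loss of Mettl3 alters signalling of tumour-exposed macrophages, with Spred2, an inhibitor of the ERK pathway, as a gene of interest. Spred2 (chromosome 11, 19924375 to 20024026) stood at 47.2 and 35.7 CPM in the controls and at 40.6 and 38.5 CPM in the knockouts. Its log2 fold change was -0.07 ± 0.20 (SE, n = 2 per group; edgeR unadjusted p = 0.753, adjusted p = 1), with -0.22 within number 1 and 0.11 within number 3. It turned to 0.154 without control 1, and was -0.255 without control 3 and -0.03 without knockout 3. Spred2 was picked from knowledge of the study, so it is not independent evidence. The list of ERK feedback genes and targets had 12 of its 17 tested members below 0 and a median log2 fold change of -0.26, -0.22 within number 1 and -0.31 within number 3, and was not called (camera in limma, adjusted p = 0.144). With the replicate block it was called (camera in limma, adjusted p = 0.0443), but not once the correlation was estimated as well (adjusted p = 0.798). NF-kB targets (29 tested) had a median of 0.04, with -0.24 within number 1 and 0.27 within number 3 (adjusted p = 0.592 by camera in limma). STAT3 targets (19 tested) had a median of -0.15, and 15 members lay below 0 (adjusted p = 0.281 by camera in limma). Among their most abundant members, Il1b stood at 2213 and 891.1 CPM in the controls and at 1540 and 1239 CPM in the knockouts. Mcl1 stood at 1144 and 760.7 CPM in the controls and at 1016 and 1143 CPM in the knockouts. Fos stood at 87.5 and 170.4 CPM against 59.4 and 122.6 CPM, a log2 difference of -0.56 within number 1 and -0.48 within number 3.

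Genes induced by interferon stood higher in the knockout macrophages, with the smallest adjusted p of the 37 lists by camera at the preset correlation. Of the 42 tested members of the interferon-stimulated list, 41 had a fold change above 0, with Irf9, a subunit of the interferon-activated ISGF3 complex, the exception. Both knockouts lay above both controls for 35 members, 83.3% of the list, where chance gives 16.7%. The list rose with a median log2 fold change of 0.84, and with 0.59 within number 1 and 1.17 within number 3 (camera in limma, adjusted p = 3.55e-41). That call was lost when the correlation between genes was estimated (camera in limma, adjusted p = 0.754 with an estimated correlation). With few degrees of freedom, that test called 0 of the 37 lists, so the lost call does not show that the list did not move. Camera in limma also called the list between library numbers, with a median of 0.31 in number 3 against number 1 (adjusted p = 2.05e-04). That call too was lost with an estimated correlation (camera in limma, adjusted p = 0.992). No member passed edgeR over all genes, and 26 passed when adjusted over the list alone. DESeq2 called 8 members over all genes, all higher. Ifit2, an antiviral protein that binds RNA, had a log2 fold change of 1.91 ± 0.30 (SE, n = 2 per group), from 19.96 and 20.9 CPM in the controls to 57.6 and 96.1 CPM in the knockouts (DESeq2 adjusted p = 5.16e-05). Ifit1 had a log2 fold change of 1.57 ± 0.26 and Rtp4 one of 1.23 ± 0.21. Isg15, a ubiquitin-like modifier, stood at 24.5 and 29.6 CPM in the controls and at 49.3 and 120.0 CPM in the knockouts. Bst2 stood at 85.2 and 145.6 CPM in the controls and at 132.0 and 204.2 CPM in the knockouts. The macrophage identity list had a median of -0.08 in the same comparison.

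**Figure D1:**
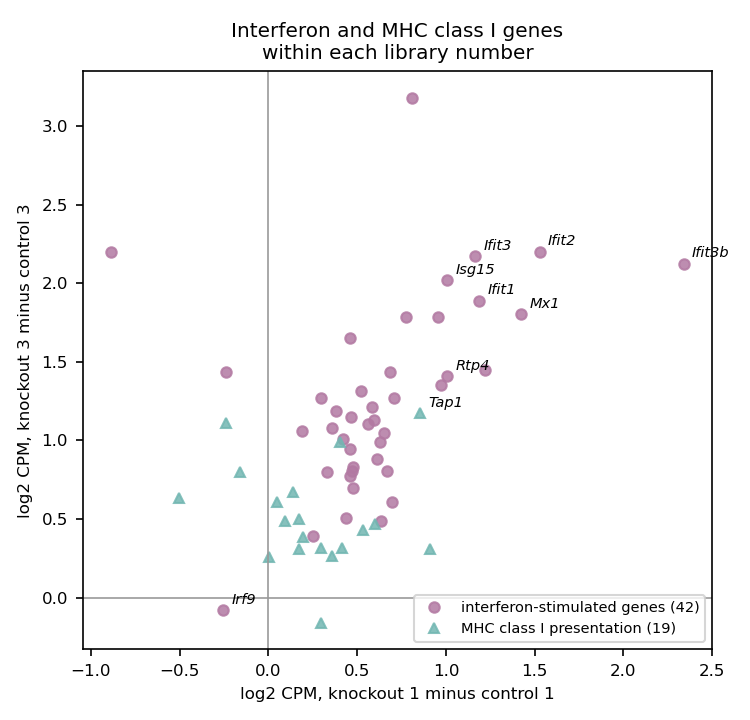
Each point is a gene of the interferon-stimulated list (42 circles) or the MHC class I list (19 triangles); the horizontal axis is the log2 CPM of knockout 1 minus control 1 and the vertical axis that of knockout 3 minus control 3. Of the interferon-stimulated genes, 39 lay above 0 on both axes.

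Genes of MHC class I presentation moved with them. All 19 tested members had a fold change above 0, both knockouts lay above both controls for 10 of them (52.6%, against 16.7% by chance), and 0 passed edgeR when adjusted over the list alone. The list rose with a median log2 fold change of 0.33, 0.20 within number 1 and 0.47 within number 3 (camera in limma, adjusted p = 1.45e-08; adjusted p = 0.754 with an estimated correlation). The abundant members moved little: B2m stood at 1831 and 2065 CPM in the controls and at 2064 and 2562 CPM in the knockouts, and H2-D1 at 2328 and 2015 against 2337 and 2406 CPM. Without knockout 3 the median of this list was 0.185. At the preset correlation, both this list and the interferon list held their call with any 1 library left out, where the lone library of a group is assumed to vary like the other group.

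Single genes outside these lists also stood higher in the knockouts. Tlr4, the receptor for bacterial lipopolysaccharide (chromosome 4, 66827584 to 66930284), was 8.02-fold higher in the knockouts, at 170.9 and 110.7 CPM against 23.1 and 12.03 CPM. Its log2 fold change was 3.00 ± 0.43 (SE, n = 2 per group), with 2.89 within number 1 and 3.20 within number 3 (edgeR unadjusted p = 0.00128; DESeq2 adjusted p = 7.13e-09). Trim25 (chromosome 11, 88999376 to 89020293), a ubiquitin ligase that acts on the RNA sensor RIG-I, stood at 97.7 and 97.6 CPM in the controls and at 249.7 and 261.8 CPM in the knockouts. Its log2 fold change was 1.39 ± 0.15 (SE, n = 2 per group; edgeR unadjusted p = 3.44e-04; DESeq2 adjusted p = 7.68e-07). Dram1, a p53-induced regulator of autophagy, had a log2 fold change of 1.82 ± 0.29, and Nagpa, an enzyme of lysosomal enzyme targeting, one of 1.09 ± 0.15. Fam110b went from 0.681 and 0.727 CPM to 4.58 and 5.40 CPM. H2-T24, a class Ib MHC gene, had a log2 fold change of 0.99 ± 0.17. The remaining 3 genes of the 12 with the smallest p, BC147527, Rps13-ps2 and Tpm3-rs7, had log2 fold changes of 2.72, 1.36 and 1.25; the last 2 are copies of Rps13 and Tpm3 whose reads may be split with the parent genes.

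Of the genes lower in the knockouts, predicted symbols aside, the zinc finger gene Zfp422 had the smallest p by edgeR. Zfp422 (chromosome 6, 116624016 to 116628999) stood at 19.7 and 13.7 CPM in the controls and at 2.06 and 2.27 CPM in the knockouts, a 7.70-fold difference (log2 fold change -2.95 ± 0.31; SE, n = 2 per group; DESeq2 adjusted p = 9.04e-12). Spcs2, a subunit of the signal peptidase, had a log2 fold change of -1.62 ± 0.18, and Napg, which acts in vesicle fusion, one of -1.45 ± 0.18. Alg2, a mannosyltransferase of N-glycan assembly, had a log2 fold change of -1.93 ± 0.26. Neat1, the long noncoding RNA that scaffolds paraspeckles (chromosome 19, 5824708 to 5845478), stood at 528.9 and 561.3 CPM in the controls and at 245.9 and 193.1 CPM in the knockouts. Its log2 fold change was -1.31 ± 0.20 (SE, n = 2 per group; edgeR unadjusted p = 0.00157; DESeq2 adjusted p = 2.27e-04), and it overlaps 3 annotated genes on its own strand. Nppa had a log2 fold change of -3.32 ± 0.58, Amigo1 one of -1.70 ± 0.32 and Sel1l3 one of -1.10 ± 0.19. Atxn7, Phf3 and Sphk2 had log2 fold changes of -0.99, -0.91 and -0.81. Hbb-bt, a beta globin, stood at 1.40 and 0.662 CPM in the controls and at 0 in both knockouts.

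**Figure D2:**
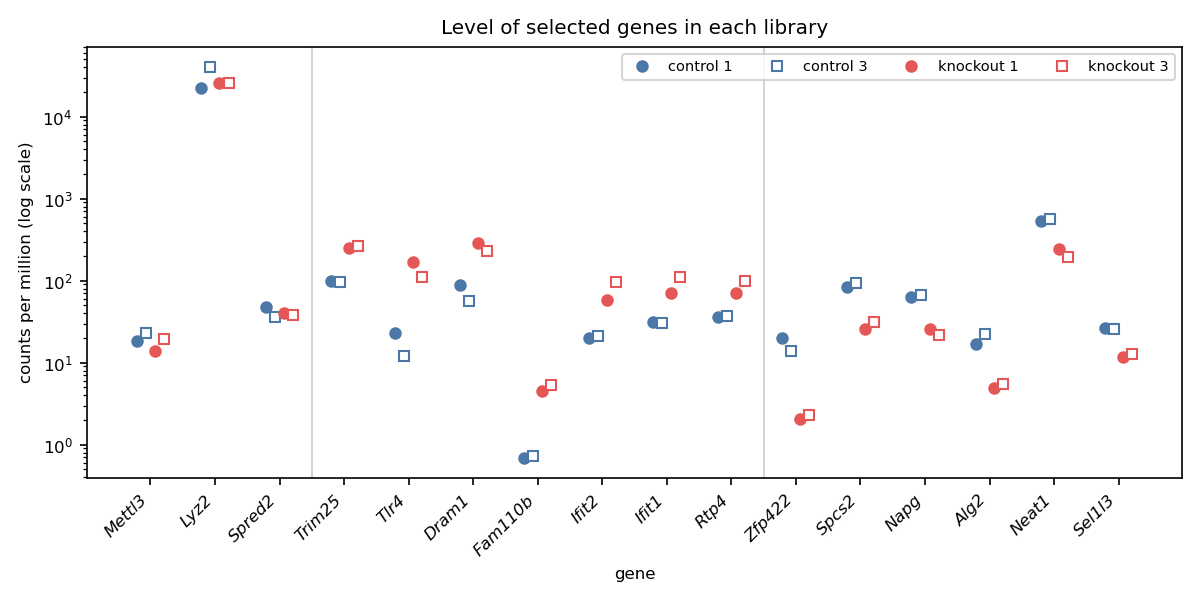
CPM (log scale) of 16 genes in each of the 4 libraries, with controls in blue, knockouts in red, number 1 as filled circles and number 3 as open squares. Mettl3, Lyz2 and Spred2 overlapped between the groups, while the knockouts stood above the controls for the next 7 genes (Tlr4 at 170.9 and 110.7 against 23.1 and 12.03 CPM) and below them for the last 6.

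By the test, edgeR called 0 of 17260 genes at an adjusted p under 0.05, with 391 genes at an unadjusted p under 0.05. That is below the share of 0.05 that unchanged genes would give. DESeq2 called 74 of 25066 genes with an unadjusted p (42 higher and 32 lower in the knockouts, 607 at an unadjusted p under 0.05). Its own filter on low counts can leave part of those genes without an adjusted p. Those 74 included all 12 named genes that were higher and 10 of the 12 that were lower (Sphk2 and Phf3 were not called). Of the 74, 12 had a count above 12 in 1 library only, and 23 had predicted symbols. Both knockouts lay above both controls for 13.1% of all tested genes and below them for 13.4%, where chance gives 16.7% each way. This chance value treats the 4 libraries as alike, which the difference between library numbers contradicts.

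The mixed mast cell to megakaryocyte list, the fibroblast markers and the matrix genes were lower in the knockouts as lists. The list of mast cell, basophil, erythroid and megakaryocyte markers (9 tested) fell with a median log2 fold change of -1.43, -0.76 within number 1 and -1.73 within number 3 (camera in limma, adjusted p = 2.75e-04; adjusted p = 0.754 with an estimated correlation). Both knockouts lay below both controls for 6 members (66.7%, against 16.7% by chance), and 2 passed edgeR when adjusted over the list alone. The 6 were 4 globin genes, Pf4 and the integrin gene Itga2b, while Kit and Prg2, chosen after their values were seen, had log2 fold changes of 0.33 and 0.97. The mast cell and basophil genes Cpa3, Fcer1a, Mcpt8 and Ms4a2 had too few counts to test, so no fall of mast cells was shown. The megakaryocyte genes Gp9 and Gp1bb, chosen after their values were seen, also had too few counts, so no fall of megakaryocytes was shown. Pf4, also known as platelet factor 4, stood at 561.1 and 654.2 CPM in the controls and at 356.0 and 361.7 CPM in the knockouts (edgeR unadjusted p = 0.00861), while the globin Hbb-bs stood at 2.95 and 1.53 CPM against 1.47 and 0.126 CPM. Without control 3 that call was lost (camera in limma, median -0.645, adjusted p = 0.0583), and the median was -0.945 without control 1 and -0.771 without knockout 3. Fibroblast and stromal markers (20 tested) fell with a median of -0.54, -0.41 within number 1 and -0.58 within number 3, and 19 members lay below 0 (camera in limma, adjusted p = 8.38e-04; adjusted p = 0.754 with an estimated correlation). Col1a1 stood at 146.2 and 313.0 CPM in the controls and at 113.3 and 189.5 CPM in the knockouts, so the groups overlapped, with -0.37 within number 1 and -0.72 within number 3. Of the 20 fibroblast markers, 18 lay below 0 within both numbers. Both knockouts lay below both controls for 1 of them (5%, against 16.7% by chance and 13.4% of all tested genes). The list also differed between library numbers (median 1.19 in number 3 against number 1). Such a difference makes the groups overlap, and leaving out 1 library mixes it with genotype. The low share therefore says little about genotype in this list. It lost its call without knockout 1 (median -0.10), turned to 0.135 without control 3, and stood at -1.03 without control 1 and -1.36 without knockout 3. The matrix remodelling and angiogenesis list (32 tested) fell with a median of -0.20, -0.30 within number 1 and -0.27 within number 3, and 25 members lay below 0 (camera in limma, adjusted p = 0.0150; adjusted p = 0.754 with an estimated correlation). Thbs1, a matrix glycoprotein, stood at 8675 and 6451 CPM in the controls and at 5124 and 4462 CPM in the knockouts, and Tgfbi at 1156 and 1041 against 661.2 and 904.0 CPM. The matrix list lost its call without control 3 (median -0.05), turned to 0.024 without knockout 1, and stood at -0.41 without control 1 and -0.50 without knockout 3. In these 2 lists 0 members passed edgeR when adjusted over the list alone.

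The 13 mitochondrially encoded mRNAs fell as a list, with a median log2 fold change of -0.29, -0.49 within number 1 and -0.13 within number 3 (camera in limma, adjusted p = 8.38e-04; adjusted p = 0.754 with an estimated correlation). The 7 genes that have a near-identical nuclear copy had a median of -0.52, and 6 of them had both knockouts below both controls. The other 6 mRNAs had a median of -0.05, and 1 of them had both knockouts below both controls. The summed level of the 7 differed by -0.47 within number 1 and -0.06 within number 3, and that of the other 6 by -0.30 and 0.11. The call was lost without control 1 (median -0.28) and without knockout 1 (median -0.07), and the median was -0.53 without knockout 3. mt-Atp6 stood at 5233 and 3985 CPM in the controls and at 2581 and 3346 CPM in the knockouts, and mt-Co1 at 14540 and 14120 against 13060 and 14590 CPM. On chromosome 1, 7 nuclear copies of mitochondrial genes, each 99.7% to 100% identical to its mitochondrial counterpart over the aligned part, had fold changes above 0, with a median of 2.52. DESeq2 called 6 of these copies. Because the sequences are so alike, the counts of the 7 copies and of the matching mRNAs are uncertain. Cytosolic ribosomal protein genes (50 tested) fell with a median of -0.09, -0.06 within number 1 and -0.11 within number 3, and 42 lay below 0 (camera in limma, adjusted p = 0.0152; adjusted p = 0.933 with an estimated correlation). Rplp1 stood at 341.3 and 266.1 CPM in the controls and at 340.8 and 240.7 CPM in the knockouts, and Rps15 at 345.5 and 287.6 against 287.2 and 262.3 CPM. Both knockouts lay below both controls for 16% of the ribosomal list, against 16.7% by chance and 13.4% of all tested genes. That list turned to 0.042 without control 1 and to 0.025 without knockout 3, and stood at -0.18 without control 3 and -0.21 without knockout 1. Apoptosis genes (26 tested) rose with a median of 0.10, 0.09 within number 1 and 0.32 within number 3, and 18 lay above 0 (camera in limma, adjusted p = 0.0243; adjusted p = 0.754 with an estimated correlation). Bcl2a1b, a survival factor of the Bcl2 family, stood at 83.6 and 64.2 CPM in the controls and at 94.3 and 95.6 CPM in the knockouts. The apoptosis call was lost without control 3, knockout 1 or knockout 3, at medians of 0.063, 0.153 and 0.11, and the median was 0.263 without control 1. In these 3 lists 0 members passed edgeR when adjusted over the list alone.

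The other 29 lists were not called, at adjusted p of 0.103 to 0.966 by camera in limma, the ERK, NF-kB and STAT3 lists among them. Toll-like receptor signalling (24 tested) had a median of 0.07, and Tlr4 was its 1 member to pass edgeR adjusted over the list alone. Cd14, the co-receptor of Tlr4, stood at 1525 and 914.1 CPM in the controls and at 1195 and 1118 CPM in the knockouts. Classical (M1) activation markers had a median of 0.15, with -0.20 within number 1 and 0.59 within number 3, and alternative (M2) markers one of -0.08. Arg1, an M2 marker, differed by library number, at 3723 and 285.5 CPM in the controls and at 2795 and 293.2 CPM in the knockouts. Marco, a scavenger receptor, stood at 2058 and 3893 CPM in the controls and at 3128 and 8204 CPM in the knockouts. Chemokines had a median of -0.15, chemokine and cytokine receptors one of -0.07 and immune checkpoint genes one of 0.04. Siglece, an inhibitory receptor, stood at 385.1 and 229.1 CPM in the controls and at 451.2 and 494.2 CPM in the knockouts.

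No list of the m6A machinery was called. The writer complex (9 tested) had a median of 0.09, readers and erasers (15 tested) one of 0.10 and m6A targets reported in immune cells (13 tested) one of 0.16. Wtap, the adaptor that recruits Mettl3, stood at 147.2 and 135.1 CPM in the controls and at 96.8 and 111.0 CPM in the knockouts (edgeR unadjusted p = 0.0419, adjusted p = 1). Virma stood at 96.8 and 92.4 CPM against 104.1 and 114.7 CPM. Of the metabolic lists, cholesterol synthesis had a median of -0.07, lipid handling one of -0.09, glycolysis and hypoxia one of -0.03 and nuclear oxidative phosphorylation one of -0.04. Lysosome and autophagy genes had a median of -0.07, NRF2 targets one of -0.10 and the integrated stress and unfolded protein response one of 0.01. Hspa5, a chaperone of the endoplasmic reticulum, stood at 632.1 and 448.2 CPM in the controls and at 803.3 and 993.7 CPM in the knockouts (edgeR unadjusted p = 0.0376, adjusted p = 1). Cell cycle genes (36 tested) had a median of 0.23, but 0.55 within number 1 and -0.35 within number 3. The medians were 0.03 for p53 targets and -0.18 for immediate early genes.

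Markers of the cell types that could be present gave the following values. Macrophage identity genes (24 tested) had a median of -0.08, and Adgre1, which encodes F4/80, stood at 4847 and 6418 CPM in the controls and at 6087 and 7501 CPM in the knockouts. Efferocytosis and complement genes had a median of 0.02 and MHC class II genes one of 0.01. Neutrophil markers had a median of 0.17, dendritic cell markers one of 0.08 and lymphocyte markers one of 0.42. Carcinoma markers (8 tested) had a median of 0.24, and the most abundant of them, Sfn and Krt19, stood at or below 1.79 CPM in every library. The keratins Krt8 and Krt18 and the adhesion gene Epcam, chosen after their values were seen, had a count of 0 in all 4 libraries, which allows up to 0.218 CPM in the shallowest. Median, mean and test differed in sign for 8 of the lists that were not called: the m6A writer complex, m6A targets, M2, immune checkpoint, oxidative phosphorylation, p53, carcinoma and neutrophil lists.

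**Figure D3:**
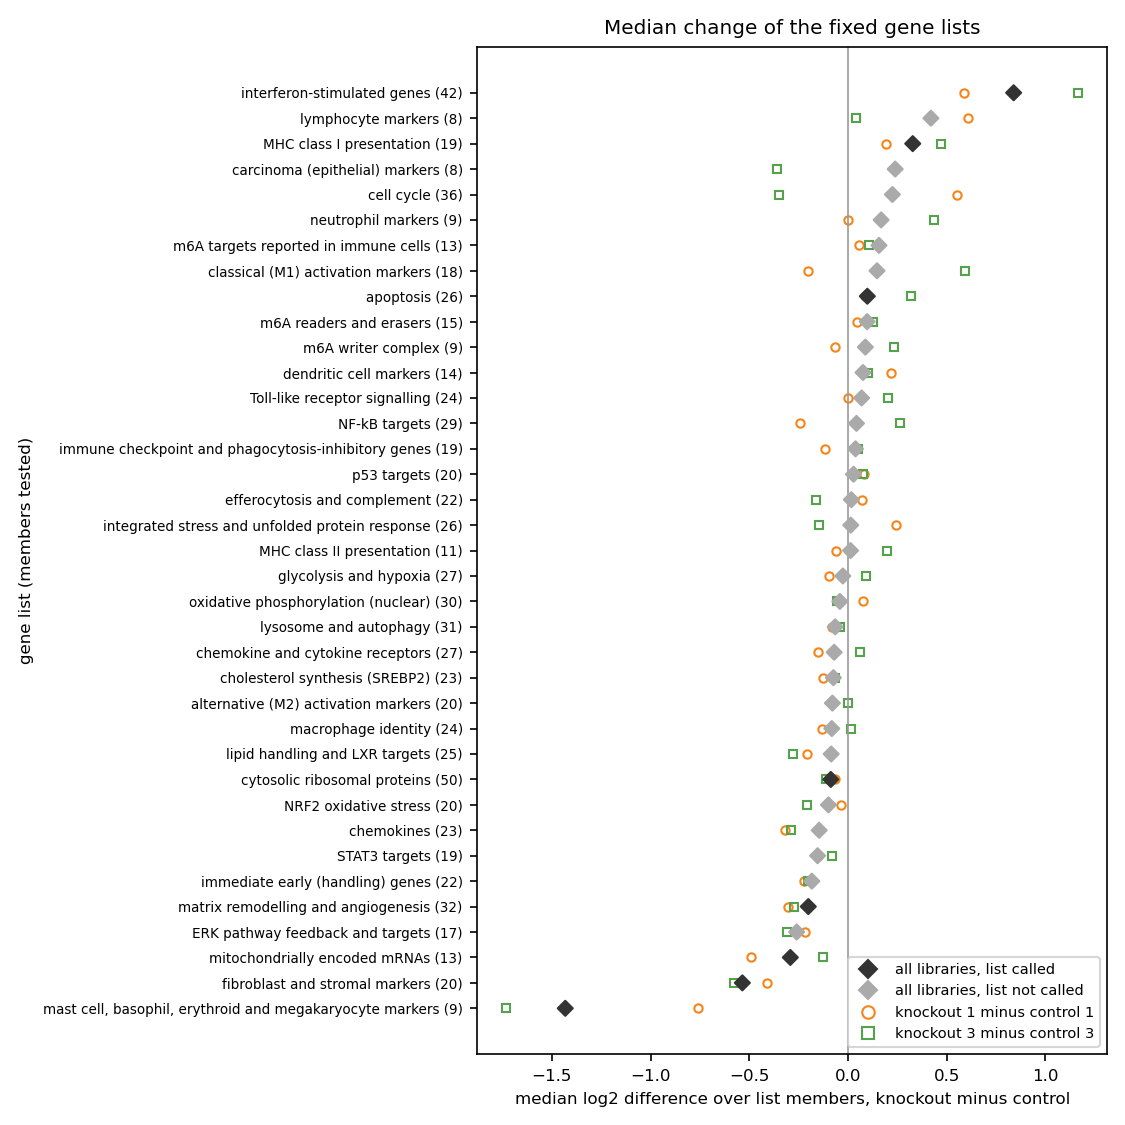
Median log2 difference between knockout and control over the tested members of each of the 37 lists, with the number tested in parentheses. Diamonds are edgeR fold changes over all 4 libraries (dark where camera called the list), circles the difference within number 1 and squares that within number 3. The interferon-stimulated list sits at 0.84, 0.59 and 1.17, and the macrophage identity list at -0.08, -0.13 and 0.02.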

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

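The tests of the interferon list and of the nuclear copies given here were chosen after the results were seen. Lyz2 had opposite differences between knockout and control within the 2 library numbers, and its log2 difference in number 3 minus that in number 1 was -0.868. Spred2 also went opposite ways, and the corresponding value was 0.326. With 1 library per genotype and number, neither difference was tested.

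For the higher interferon-stimulated list in the knockouts, the tables argue against a single library as the source, since the lowest median with 1 library left out was 0.579. Fibroblast markers (median -0.54) and a mixed list whose lower members were globin genes, Pf4 and Itga2b (median -1.43) were lower in the knockouts. The mixed list shows no fall of a cell type, since many of its markers had too few counts to test. A lower share of other cells would raise macrophage genes alike. The macrophage identity list had a median of -0.082 (SD over 24 members 0.268), which argues against this source. Variation between mice or cultures stays open. The largest absolute median of the other 2 splits of the libraries was 0.311, against 0.807 for the real split on the same scale. Camera in limma also called the list in that other split, number 3 against number 1 (adjusted p = 2.05e-04). Like the call between genotypes, it was lost with an estimated correlation (camera in limma, adjusted p = 0.992), a test that could call few lists from 4 libraries. In addition, 3 splits are too few for a share under 0.05. Library scaling had also been listed and was dropped after its values had been seen; the median was 0.579 to 1.124 over all settings, scalings included. Loss of Mettl3 is the biological explanation that the design names, and may act together with differences between mice that these 4 libraries cannot separate.

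The 7 nuclear copies of mitochondrial genes on chromosome 1 had a median log2 fold change of 2.52. The median of the 13 mitochondrially encoded mRNAs was -0.292, but 7 of them may share reads with the copies. The other 6, with a median of -0.049, argue against more mitochondrial RNA in the knockout libraries. Their summed level differed by -0.304 within number 1 and by 0.109 within number 3. Reads shared with the mitochondrial genes stay open, since the sequences were 99.7% to 100% identical. The summed level of the copies and the 7 genes they match differed by -0.10 within number 1 and by 0.147 within number 3, while the copies alone differed by 2.501 and 1.98. With the 7 genes unchanged the sum would have differed by only 0.261 and 0.196, so a bound of 0.25, found too wide after the test was run, cannot tell shared reads from a rise of the copies.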

How the results depend on the processing

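Settings marked as added were chosen after the data were seen. Without a replicate block edgeR called 0% of simulated 2-fold and 4-fold changes, so its 0 does not show that no gene changed. Among 22 other settings, most of them without the block, the count of 0 changed genes held in 20. It was 74 with DESeq2 (42 higher, 32 lower) and 175 with DESeq2 and a replicate block (added; 107 higher, 68 lower), and 60 genes were called in both. Of the 24 named genes other than Mettl3, Lyz2 and Spred2, all kept their sign in every setting that tested them. With DESeq2 22 passed the threshold, and 24 with DESeq2 and the block. The 24 were chosen for a small p in these same libraries, and for each both knockouts lay beyond both controls. A kept sign or a DESeq2 call is therefore not independent support. The cause of the differing gene counts was not tested. Where 1 library was left out, number was mixed with genotype, and the lone library of a group was assumed to vary like the other group. This gave 0 genes each time, a log2 fold change of -0.584 to -0.07 for Mettl3, -0.665 to 0.215 for Lyz2 and -0.255 to 0.154 for Spred2. Lyz2 was also at 0 after quantile normalization, which was first labelled a change of sign; the rule was altered after this was seen. Of the 37 lists, 8 were called, 0 with an estimated correlation, 0 by fry, and 7 to 15 with 1 library left out, the highest without control 1. List medians with 1 library left out ran from 0.579 to 1.124 for interferon-stimulated genes and from 0.185 to 0.475 for MHC class I. They ran from -0.50 to 0.024 for matrix remodelling, -1.36 to 0.135 for fibroblast markers and -0.213 to 0.042 for ribosomal proteins. The last 3 changed sign, but number was mixed with genotype there. Within numbers 1 and 3 they stayed below 0 (matrix -0.303 and -0.274, fibroblast -0.409 and -0.575, ribosomal -0.064 and -0.111). The list of mast cell to megakaryocyte markers had under 5 members tested in 7 settings that filter on FPKM, and was not tested there; these settings had first been labelled as lost calls, and were dropped after this was seen. It lost its call without the count filter (adjusted p = 0.239 by camera in limma). By the labels the libraries share only a number. By Xist and Y-linked levels, number 1 had the pattern of male cells and number 3 that of female cells. Deviations from the group means correlated at 0.419 between libraries of the same number. With edgeR and the replicate block 0 genes were called (929 at an unadjusted p under 0.05, against 391). Unchanged genes would give a share of 0.05, and of 17260 tested genes 929 is near that share and 391 below it. The blocked fit called 73.1% of simulated 4-fold and 71.2% of 8-fold changes. It did not call Tlr4, 8.02-fold higher in the knockouts (edgeR with the block, adjusted p = 0.356). The simulation may therefore overstate the power on the real counts, and the 0 does not show that large changes are absent. Camera on this fit called 9 lists. With an estimated correlation 0 of them were called, but that test has few degrees of freedom, fewer still with the block. The ninth was the ERK list (camera in limma, adjusted p = 0.0443; adjusted p = 0.798 with an estimated correlation); the 8 lists kept their call, fibroblast markers at an adjusted p of 1.4e-10. Limma on log2(FPKM + 1) and limma voom, both with the replicate block (added), also called 0 genes. At an unadjusted p under 0.05 stood 728 of 11289 and 1071 of 17260 tested genes. Depth limits what is seen below 0.151 to 0.218 CPM.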

Other observations

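The comparison of library numbers and the genes named in the next 2 paragraphs were chosen after the results were seen; the 2 tests in the last paragraph were set before theirs. With genotype as a covariate, edgeR called 122 genes between the libraries numbered 3 and those numbered 1 (70 higher and 52 lower in number 3; 3044 at an unadjusted p under 0.05), of which 8 lie on X or Y. Nos2, a marker of classical activation, and Arg1, one of alternative activation, fell by 4.75 and 3.48 on the log2 scale in number 3, and H2-Ab1, an MHC class II chain, fell by 2.00. Inhba, which encodes activin A, rose by 3.91, and the stromal genes Acta2, Postn and Tnc rose by 2.31, 2.29 and 1.89 (edgeR adjusted p = 0.0303 to 0.0346 over these genes). Cell cycle genes had a median of -1.21 with all 36 members below 0, and cholesterol synthesis genes one of -0.80 with all 23 below 0. Fibroblast and stromal markers had a median of 1.19, and macrophage identity genes one of 0.05. Interferon-stimulated genes had a median of 0.31 with 33 of 42 above 0 (camera in limma, adjusted p = 2.05e-04). Camera in limma called 11 lists, among them also cell cycle, cholesterol synthesis, fibroblast, matrix remodelling (adjusted p = 0.0116) and ribosomal proteins (adjusted p = 1.14e-06), and 0 with an estimated correlation (lowest adjusted p = 0.890). Explanations of the difference had been listed and were dropped after these values had been seen, so none was tested. Ribosomal RNA made up 0.698% and 1.112% of the counts in control 1 and knockout 1, against 0.09% and 0.085% in control 3 and knockout 3. The called noncoding RNA Rn7sk stood at 14.69 and 23.58 CPM in the libraries numbered 1, against 0.8074 and 0.6064 in those numbered 3. Rn7s1 stood at 16.86 and 27.78 against 1.518 and 1.364 CPM. Whether library preparation differed between the numbers was not tested.

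Control 3 held the most counts of several transcripts made in the liver. Alb had 1248 counts, Apoa1 336, Cyp2e1 244, Fgb 115 and Ttr 106, all at 0 in the other 3 libraries. Apoa2 had 252 counts there, against 33 in control 1, 35 in knockout 1 and 3 in knockout 3.

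Donor-strain DNA around Lyz2 and Mettl3, carried along with the engineered alleles, might account for some of the genes called by DESeq2 with the replicate block. Of the 175 genes called, 5 (2.86%) lay within 10 Mb of either gene, against 1.87% of the 15966 genes given an adjusted p in that fit (one-sided Fisher exact p = 0.231). This leaves the source open. The gene set comes from a setting added after the data were seen. Controls also carry the floxed Mettl3, so by design only the Lyz2 side (1 of the 5 genes) differs between the groups. Fold changes of protein-coding genes were examined for the hypothesis that loss of methylation on long internal exons raises transcripts. Across 12418 protein-coding genes with an internal exon (93.4% of those tested), Spearman's rho between the longest internal exon in GENCODE M21 and the log2 difference was -0.014 within number 1 and 0.023 within number 3. Both lay under the bound of 0.05 set in advance, and rho between the 2 controls was -0.036. Genes are not independent replicates, so no p is given.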
